A study of Mus musculus with 3 samples.

How the data were processed

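Mouse CAD neuroblastoma cells had been transfected with control, Ptbp1, or Ptbp1 plus Ptbp2 siRNAs, and poly(A)+ RNA was taken after 72 h. Per the labels' protocols, the RNA was fragmented, copied with random primers, selected at 350 bp within 50 bp, amplified over 15 PCR cycles and read as 36-base pairs on a Genome Analyzer IIx. Such a library does not mark strand by itself. Groups came from the transfection label of each of the 3 samples, and each group had 1 library.

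The deposited table gives, for 27389 gene clusters on the mm9 build per the file headers and the submitters' processing notes, a whole-number read value per library, the exonic length and an RPKM value. The aligner, the counting tool and the gene set were not given in the sources used here. The read values behave like read counts but are net numbers: 38 clusters hold a value below 0 in at least 1 library, the lowest being -65, so the authors had subtracted something that no header or label explains. Of these clusters 37 had all values within 10 of 0 and 10 were shorter than a read. They were left out, as were 127 clusters with no length and no reads, and the other values were treated as counts, which makes the intervals approximate. The deposited RPKM values divide the read value by length and by a library total of 24167120, 25649604 and 21572838 in the order control, Ptbp1 siRNA, both siRNAs. Those totals exceed the sums over clusters, which are 66.3%, 65.9% and 66.0% of them.

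A read could enter more than 1 cluster. A nuclear copy of a mitochondrial segment on chromosome 1 (24620811 to 24621652) held 135952, 158149 and 163425 reads, and its mitochondrial source (positions 7767 to 8608) 135937, 158039 and 163312. Genes with near-identical copies or overlapping exons are therefore uncertain, and the share of exon bases covered by other genes was computed for each named gene. Starts in the table count from 0 and are printed from 1. Clusters were named from the table's aliases and the mouse GENCODE annotation of the same build. Alias and position named 16074, position alone (overlap of spans of at least 0.5 of their union) 5022 and alias alone 133, while 5995 kept their first alias. Of several clusters with 1 symbol, the 1 with the highest mean was kept, which left 26836 rows.

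Library sizes were scaled by the trimmed mean of M values (30% of M and 5% of A trimmed), computed with numpy 2.4.6, giving factors of 0.970, 1.02 and 1.01. Levels are CPM, differences are on the log2(CPM + 1) scale, which understates those of low genes, and folds are CPM ratios without the pseudocount. A gene was tested in a pair when it reached 1 CPM in the higher library. It was called by size at a 2-fold difference on that scale, provided that the exact (Clopper-Pearson, conditional binomial) 95% interval of the read ratio excluded 1. No count of 0 is reported as a fold, and a limit of 3 counts corresponds to 0.196, 0.176 and 0.211 CPM in the libraries. Mitochondrial genes held 3.73%, 3.95% and 4.68% of reads, and the top 10 genes 6.85%, 6.81% and 7.27%. The plan allowed for counts or normalized values, and the count form was used although the columns are net reads.

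On simulated data for both siRNAs against control with 13271 genes in the step, 98 of 100 genes changed 3-fold were called and 1 of 100 changed 1.5-fold, with 0 calls among unchanged genes. The intervals held the true ratio for 95.6% of genes. These simulated libraries held counting noise alone, so they give no rate of false calls between single cultures. For the overlap of the knockdowns, 100 sets of libraries without effects were drawn with counting noise against the same control.

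For 35 gene lists, 812 names in all, the median difference of measured members was set against 10000 random lists of equal size drawn from 20 bins of mean expression. Its percentile describes these libraries and is no test of the conditions. The genes named were those targeted and the study's presynaptic genes. To these were added, for each pair, the 8 largest differences per direction among called genes with at least 50 reads in the pair and an established symbol. In each list up to 4 members with the largest difference after both siRNAs were named, and for the steps 6 genes per pattern with steps of at least 0.58. Rules, lists and most alternatives were fixed before the data were examined. Named outside the rule, after their values were seen, were Vcl, as a called member of its list, the genes that lay on opposite sides of the control, and single genes such as Txnip, Malat1 and the members of the lists of hypoxia, fatty acid, ribosome biogenesis, secretory, imprinted and mitochondrial genes. Some genes that met the rule are not reported here, and the median over the presynaptic genes was taken over the 3 that are.

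The alternatives were pseudocounts of 0.1 and 5, no filter or 5 CPM, median-of-ratios and quantile scaling, limits of 1.5-fold and 3-fold, summed rows per symbol, and a binomial test of the reads of each pair with Benjamini-Hochberg adjustment, which compares the libraries and not the conditions. Added after seeing the data were library totals, the authors' totals, the deposited RPKM, no interval condition, leaving out mitochondrial or overlapping clusters, and removal of a trend in GC content, length and expression. GC content came from the longest coding transcript and was known for 91.5% of tested genes. Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Intron retention, splicing and single reads were not analysed here.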

Results

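Poly(A)+ RNA of mouse CAD cells, a catecholaminergic neuroblastoma line, was sequenced after the cells had been transfected with control siRNAs, siRNAs against Ptbp1, or siRNAs against Ptbp1 and Ptbp2 together. Ptbp1 encodes a polypyrimidine tract binding protein, an RNA-binding regulator of splicing found in most non-neuronal cells, and Ptbp2 encodes its paralogue of the nervous system. Each of the 3 groups had 1 library, taken 72 h after transfection and read as 36-base paired ends. The gene clusters of the control library held 16011466 reads, those of the Ptbp1 siRNA library 16899549 and those of the library with both siRNAs 14242495. A level of 1 CPM, the read number scaled to library size, stood for 15.3, 17.01 and 14.2 reads in these libraries, and 13414 genes reached it in at least 1 of them. With 1 library per group no difference below has a replicate check, so no p-value is given. Folds carry 95% intervals of the read ratio, which cover counting error only and no variation between cultures. Even for counting error they may be too narrow, because amplified reads without molecular identifiers are not independent molecules. Whether a value counts reads or pairs was not given, and if both reads of a pair were counted the intervals are narrower still than they should be. A gene was called higher or lower by size when its log2 difference, on the log2(CPM + 1) scale, was at least 1 in size, it reached 1 CPM and its interval excluded 1. These values are totals per gene and do not separate spliced from intron-retaining transcripts.

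The targeted genes came first. Ptbp1 (chromosome 10, positions 79317351 to 79327179 of the mm9 build) had 7191 reads in the control library, 1486 after Ptbp1 siRNA and 1516 after both siRNAs. It was 5.38-fold lower after Ptbp1 siRNA (95% counting interval 5.09 to 5.70) and 4.41-fold lower after both (4.17 to 4.67). Ptbp2 (chromosome 3, 119421465 to 119486177) had 784, 3044 and 633 reads, so it was 3.49-fold higher after Ptbp1 siRNA than in the control (3.23 to 3.78). With its own siRNA added it was 4.02-fold lower than after Ptbp1 siRNA alone (3.69 to 4.39) and 1.15-fold lower than in the control (1.04 to 1.28). Rod1, the older symbol of the third family member Ptbp3 (chromosome 4, 59484912 to 59562159), had 2284, 2372 and 1744 reads, with log2 differences from the control of -0.10 and -0.28. The family's list of 3 genes had median differences of -0.10, -0.28 and -0.18 in the 3 pairs. These are the values of Rod1 itself and do not describe the family as a set. About 16% of the exon bases in the Ptbp1 cluster are shared with neighbouring or antisense genes, whose reads cannot be told apart without strand.

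The series concerned neuronal transcripts whose steady-state levels depend on regulated intron retention, and presynaptic genes known from that work were followed. The 3 reported were higher in both knockdown libraries than in the control. Vamp2, which encodes a vesicle SNARE protein (chromosome 11, 68902031 to 68905884), had 1296, 2723 and 3510 reads and was 1.89-fold (1.77 to 2.02) and 2.91-fold higher (2.73 to 3.10). Kif5a, a kinesin motor gene of neurons (chromosome 10, 126662756 to 126700137), had 795, 1802 and 2055 reads and was 2.04-fold (1.87 to 2.22) and 2.78-fold higher (2.56 to 3.02). Sv2a, a synaptic vesicle glycoprotein gene (chromosome 3, 95985151 to 95999104), had 430, 861 and 617 reads and was 1.80-fold (1.60 to 2.03) and 1.54-fold higher (1.36 to 1.75). Their median log2 difference was 0.91 after Ptbp1 siRNA and 1.46 after both siRNAs, each at percentile 100 of 10000 random lists matched on expression. Between the knockdown libraries Vamp2 and Kif5a were higher after both siRNAs by 0.62 and 0.44, while Sv2a differed by -0.22. These genes were chosen by the study, so they are not independent evidence of their direction.

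**Figure D1:**
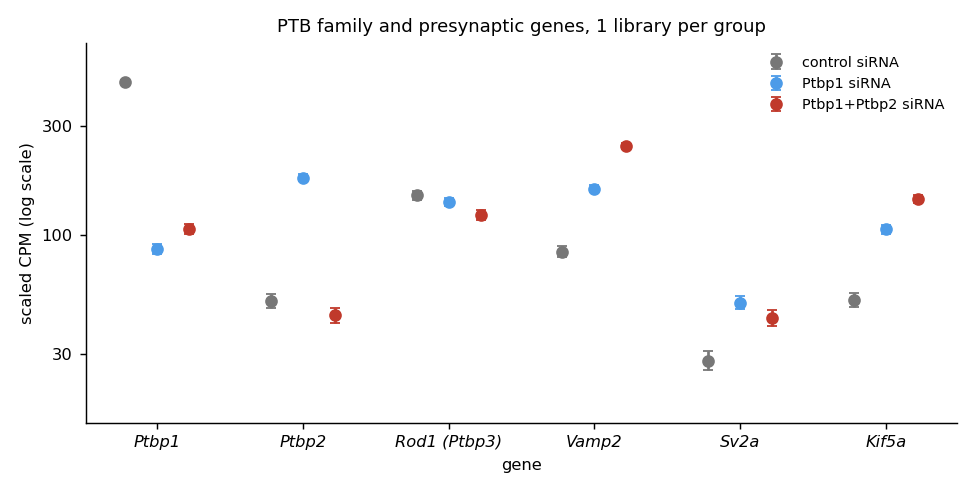
Level of the PTB family and of 3 presynaptic genes (x axis) in scaled CPM on a log axis, with 1 point per library and bars for the 95% counting interval. Ptbp1 was at 470.1 CPM in the control library against 87.3 and 106.5 in the knockdown libraries, Ptbp2 stood highest after Ptbp1 siRNA alone at 178.9, and Vamp2 went from 84.7 through 160.1 to 246.6.

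Ptbp1 siRNA against control siRNA shows what accompanied the loss of Ptbp1 while Ptbp2 was high. The largest differences were lower values of Flna, Lepre1, Fkbp14 and Fbln2, and higher values of Ptbp2, of the noncoding RNAs Meg3 and Rian and of A2bp1. DNA replication genes were higher as a group, and cholesterol synthesis and glycolysis genes were lower. Of 13240 genes tested, 37 were higher and 61 lower by size, and 93.6% of all tested genes lay within 1.5-fold. Flna, the gene of the actin cross-linker filamin A (chromosome X, 71468801 to 71491874), was 6.35-fold lower (6.05 to 6.66), more than Ptbp1 itself. Lepre1 and Fkbp14, whose products modify and fold collagen in the endoplasmic reticulum, were 4.42-fold (3.84 to 5.10) and 3.08-fold lower (2.72 to 3.50). Fbln2, the gene of an extracellular matrix fibulin, was 4.42-fold lower (3.83 to 5.11). Grap2 was 4.06-fold lower (2.76 to 6.12), from 124 reads in the control library.

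Among the genes that were higher, Ptbp2 had the largest log2 difference, 1.78. Meg3 and Rian, noncoding RNAs of an imprinted cluster on chromosome 12, went from 18 to 98 and from 60 to 181 reads, which is 4.90-fold (2.94 to 8.60) and 2.71-fold higher (2.02 to 3.70). A2bp1, the older symbol of the neuronal splicing factor gene Rbfox1 (chromosome 16, 5885092 to 7411612), was 3.79-fold higher (2.64 to 5.54). Hrh3, which encodes a histamine receptor, was 4.26-fold higher (2.70 to 7.0), and Kif21b, a neuronal kinesin gene, 4.80-fold (2.56 to 9.76). Myh7, the slow and cardiac myosin heavy chain gene, and Evpl, the envoplakin gene, were 4.59-fold (2.30 to 10.1) and 3.65-fold higher (2.09 to 6.76). Apart from Ptbp2 and Rian, these genes rested on 38 reads or fewer in the control library, and 12% of the exon bases of Hrh3 are shared with another gene.

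Of the 35 gene lists fixed before the data were examined, 11 had medians outside the central 95% of random lists in this pair. The study's presynaptic genes were among them. Random lists would give 1.75, but the genes of a list can vary together between cultures, so the excess is no evidence of an effect of the siRNAs. DNA replication genes were higher in all 29 measured members, with a median of 0.51 (percentile 100), although Mcm10, at 1.00, was the 1 member called by size. Mcm2, a subunit of the replicative helicase, was at 0.90, Prim1 at 0.69 and Rfc4, which shares 12% of its exon bases with another gene, at 0.44. Mitosis genes had a much smaller median of 0.10 over 28 members, at percentile 99.9. Cholesterol synthesis genes were lower in all 24 measured members with a median of -0.44, and glycolysis genes in all 19 with a median of -0.37, both at percentile 0, and in neither list did a member reach the size for a call. Muscle and contractile genes had a median of -0.16 (percentile 0.87), with 4 of 28 members called lower and none higher. The 4 genes with exons that PTBP1 is known to tie to mRNA decay had a median of -0.60 (percentile 0.07). They went both ways, so the median does not describe them as a set, and no direction had been fixed for each gene. Hps1 and Bak1 were 2.19-fold (1.93 to 2.50) and 2.13-fold lower (1.85 to 2.44), Gabbr1 was 1.99-fold higher (1.83 to 2.17), and Dlg4 was at -0.15. Without Bak1, whose cluster overlaps another, the median was -0.16. The 4 astrocyte markers measured were all below 0, with a median of -0.45 (percentile 0.23) that became -0.18 with no filter on low values. Dense core granule genes (median -0.26, percentile 0.38) and ribosomal protein genes (-0.14, percentile 0.79) lay below the random lists, and nuclear exosome and nuclear pore genes (0.09, percentile 97.54) just above. These medians were reduced to -0.12 under quantile scaling, -0.07 under library-total scaling and 0.04 without overlapping clusters.

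Library-total scaling in place of the trimmed mean gave 50 higher and 48 lower genes, a share of 51.0% higher against 37.8%. A pseudocount of 0.1 CPM gave 158 and 138 genes and a pseudocount of 5 CPM gave 4 and 26.

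Ptbp1 and Ptbp2 siRNAs together against control siRNA show the difference when both genes were targeted. Of these genes mainly Ptbp1 differed, as Ptbp2 RNA was near its control level (44.5 against 51.3 CPM), and protein was not measured. More genes differed than after Ptbp1 siRNA, 147 higher and 355 lower by size of 13304 tested, and 82.7% lay within 1.5-fold. Cholesterol synthesis and glycolysis genes were lower as groups, contractile genes less so, and single genes such as Flna, Lepre1, Kdelr3 and Iqgap1 were lower by far more. DNA replication genes and, less so, neuronal RNA-binding protein and transcription factor genes lay above matched random lists. Flna was again the lowest, 6.86-fold below the control (6.50 to 7.24). Lepre1 was 7.10-fold lower (5.91 to 8.60) and Kdelr3, which encodes a receptor that returns proteins to the endoplasmic reticulum (chromosome 15, 79346899 to 79358126), 6.39-fold (5.47 to 7.5). Fbln2 was 6.34-fold lower (5.31 to 7.62) and Fkbp14 4.73-fold (4.04 to 5.57). Iqgap1, the gene of an actin-binding scaffold (chromosome 7, 87857672 to 87948181), had 4499, 2279 and 708 reads in the 3 libraries and was 5.91-fold lower (5.46 to 6.41). Cnn2, a calponin gene, was 4.61-fold lower (4.0 to 5.33).

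On the other side, Meg3 was 8.42-fold higher after both siRNAs than in the control (5.14 to 14.6), with 141 reads against 18, and A2bp1 was 5.29-fold higher (3.72 to 7.71). Tbx3, a T-box transcription factor gene (chromosome 5, 120120679 to 120134611), had 72 reads in the control library, 95 after Ptbp1 siRNA and 303 after both, a 4.52-fold difference from the control (3.49 to 5.93). Lrrc55, which encodes a potassium channel subunit, was 4.86-fold higher (3.41 to 7.11). H2-DMa, a gene of antigen presentation, was 4.51-fold higher (3.10 to 6.73) and Shbg, the sex hormone binding globulin gene, 3.52-fold (2.83 to 4.40). Pcnxl2 was 12.6-fold higher (4.62 to 48.3) on 47 reads against 4. Arhgap22 was 3.43-fold higher (2.84 to 4.15), but 40% of its exon bases are shared with another gene.

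In this pair 14 of the 35 lists had medians outside the central 95% of random lists, again including the study's presynaptic genes. The cholesterol synthesis list had the lowest median, -0.90 over 24 members, none of them above 0, and 8 were called lower. Lss, the gene of lanosterol synthase, was 3.17-fold lower (3.04 to 3.30). Insig1, a sterol-responsive regulator of sterol sensing, was 2.70-fold lower (2.60 to 2.81). Stard4, a sterol carrier gene, was 2.48-fold lower (2.30 to 2.67). Glycolysis genes had a median of -0.80 over 19 members, again none above 0, with 6 called lower. Aldoc, an aldolase gene, was 3.97-fold lower (3.64 to 4.34), the glucose transporter gene Slc2a3 2.66-fold (2.58 to 2.74), Pfkl 2.65-fold (2.55 to 2.75) and Aldoa 2.63-fold (2.57 to 2.70). Both lists were below all 10000 random lists. Oxidative phosphorylation genes had a median of -0.06 (percentile 36.0), with Ndufv2 at 0.51 and Cox6a1 at -0.40.

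The muscle and contractile list had a median of -0.28 (percentile 0.16), or -0.15 with a pseudocount of 5 CPM. Of 28 members 5 were called lower and none higher, and 8 were above 0. Among those called were genes of the general actin cytoskeleton: Flna, Cald1, the caldesmon gene, at 4.45-fold lower (4.06 to 4.88), Cnn2, and Vcl, the vinculin gene, at -1.19. Beside it, fibroblast and matrix markers had a median of -0.54 over 9 members (percentile 0.13), which depended on the filter, being -0.05 with none and -0.79 at 5 CPM, with Sparc 2.69-fold lower (2.53 to 2.85) and Col1a1 2.36-fold lower (1.68 to 3.38). Vim, an abundant gene of CAD cells with 21605 control reads, was at -0.78 and Pdgfrb at -0.79. Astrocyte markers had a median of -0.59 over 4 members (percentile 0.56), of which Aldoc is also in the glycolysis list, and Fgfr3, Slc1a2 and Glul were at -0.68, -0.49 and -0.48. Oligodendrocyte and Schwann markers had a median of 0.14 over 5 members (percentile 74.1), with Cnp at -0.30. Blood and endothelial markers had a median of -0.33 over 3 members (percentile 14.2), Pecam1 being at -0.90.

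Neuronal RNA-binding protein genes had a median of 0.43 over 13 members (percentile 99.97), with A2bp1 called higher, Celf5 at 0.94, Nova1 at 0.62 and Elavl4 at 0.61. Neuronal transcription factor genes had a median of 0.33 over 18 members (percentile 99.9), or 0.15 with no filter on low values, with Myt1 at 0.93, Insm1 at 0.92 and none called. For both lists the interval of the median over genes reached just below 0 (-0.04 to 0.62 and -0.01 to 0.46). The wider set of synaptic vesicle and exocytosis genes, without the study's genes, had a median of 0.08 over 32 members (percentile 84.96). In it Syt5 was called higher on 56 reads against 18, the complexin genes Cplx1 and Cplx2 were at 0.95 and 0.78, and Rab3d was at -0.72. Medians near 0 were also found for postsynaptic and receptor genes (0.02, percentile 58.5), voltage-gated channel genes (0.03, percentile 64.5) and neuronal cytoskeleton and transport genes (-0.08, percentile 22.8). In the last list Klc1, a kinesin light chain gene, was 2.13-fold higher (2.00 to 2.27), and Nefh and Kif5c were at 0.93 and 0.82. Camk2b was at -0.96 and Dlg2 at 0.85, and of the channel genes Scn3b was at 0.82 and Cacna1g at -0.77. Axon guidance and adhesion genes had a median of 0.17 (percentile 96.8), whose sign depended on the setting (-0.06 without overlapping clusters, 0.35 with the deposited RPKM), with Nrp1 2.73-fold (2.47 to 3.03) and Plxna4 2.11-fold higher (1.89 to 2.36) and Slit1 2.94-fold lower (2.02 to 4.35). In the catecholaminergic list (median 0.15, percentile 90.9) Dbh, which makes noradrenaline from dopamine, was 2.33-fold higher (2.22 to 2.46), and Phox2a, a transcription factor gene of noradrenergic neurons, 2.08-fold (1.95 to 2.21). The dense core granule list had a median of -0.13 (percentile 18.5), and its abundant member Vgf was 2.36-fold lower (2.32 to 2.40). Genes of the REST complex had a median of -0.01 (percentile 54.4), with Rest at -0.65.

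Among genes of RNA metabolism, SR protein and spliceosome genes had a median of 0.18 over 27 members (percentile 99.5), with Srsf1 at 0.61 and Srsf3 at 0.59. Nuclear exosome and pore genes were at 0.21 over 22 members (percentile 99.3), with Exosc2 at 0.97. Nonsense-mediated decay factors were at 0.19 over 16 members (percentile 97.7), with Magoh at 0.82, and none of these 3 lists held a called gene. Their intervals over genes also reached just below 0 (in this order, -0.01 to 0.43, -0.02 to 0.49 and -0.05 to 0.58). The hnRNP list had a median of 0.06 (percentile 81.8), and Hnrnpd was 2.23-fold higher (2.10 to 2.37). Transcripts known to be limited by nonsense-mediated decay had a median of 0.06 over 9 members (percentile 69.2), with Tbl2 at -0.88 and Snhg5 at 0.39. The 4 decay-exon genes again went both ways, and their median of -0.61 (percentile 0.55) does not describe them as a set. Hps1 was 2.83-fold (2.43 to 3.30) and Bak1 2.11-fold lower (1.83 to 2.45), Gabbr1 was 2.11-fold higher (1.94 to 2.30) and Dlg4 was at -0.19. Without Bak1 the median was -0.19.

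DNA replication genes were again high, with a median of 0.53, 28 of 29 members above 0 and Mcm10 2.09-fold higher (1.86 to 2.34), while mitosis genes had a median of -0.04 (percentile 40.4) with Ccnb1 at 0.78 and Ect2 at -0.82. Interferon response genes had a median of -0.25 over 19 members (percentile 2.14), and Tap1, Ddx58 and Stat2 were 2.46-fold (1.99 to 3.07), 2.16-fold (1.79 to 2.61) and 2.01-fold lower (1.88 to 2.16). Genes of the p53 response had a median of -0.11 (percentile 19.0), with Btg2 2.81-fold (2.35 to 3.38) and Trp53inp1 2.52-fold lower (2.07 to 3.09). The unfolded protein and amino acid response list had a median of 0.00 (percentile 63.5), although Ddit4, a stress-induced regulator of mTOR signalling, was 2.46-fold lower (2.39 to 2.53). Immediate early genes had a median of -0.05 (percentile 33.4), with Myc 2.25-fold higher (2.07 to 2.44) and Ier3 2.42-fold lower (2.16 to 2.70). Ribosomal protein genes had a median of -0.11 (percentile 13.3), with Rps15 at -0.76, replication-dependent histone genes of -0.18 (percentile 18.8), and housekeeping genes of -0.17 (percentile 5.44). The transferrin receptor gene Tfrc, listed among the last, was 2.30-fold higher (2.13 to 2.48).

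**Figure D2:**
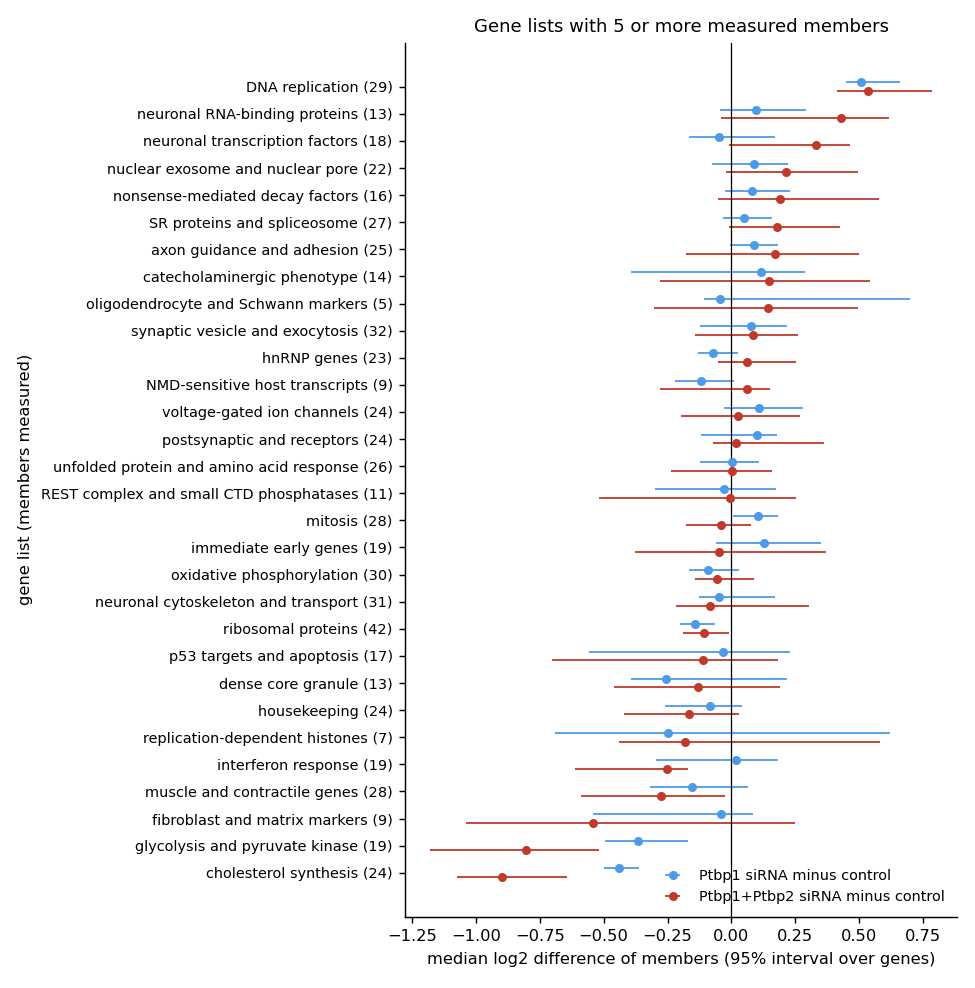
Median log2 difference from the control library (x axis) of the 30 gene lists with 5 or more measured members (y axis, number measured in brackets), for Ptbp1 siRNA and for both siRNAs. Bars are 95% intervals of the median over genes, not over replicates. Cholesterol synthesis and glycolysis lie lowest, at -0.90 and -0.80 after both siRNAs, and DNA replication highest, at 0.53.

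With library-total scaling 193 genes were higher and 286 lower, a share of 40.3% higher against 29.3%. Pseudocounts of 0.1 and 5 CPM gave 350 and 45 higher genes. A limit of 1.5-fold gave 992 higher and 1312 lower, a share of 43.1% higher.

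Both siRNAs against Ptbp1 siRNA alone shows what differed between single cultures with and without Ptbp2 siRNA, in which Ptbp1 also differed (106.5 against 87.3 CPM). Apart from Ptbp2 itself the largest differences included lower Iqgap1, Ddr2 and Gdf15 and higher Tbx3, and the cholesterol and glycolysis lists were lower once more. Of 13301 genes tested, 14 were higher and 44 lower by size, and 94.7% lay within 1.5-fold. Iqgap1 was 2.69-fold lower (2.47 to 2.93), Ddr2, a collagen receptor kinase gene, 2.56-fold (2.30 to 2.86) and Gdf15, a stress-responsive cytokine gene, 2.41-fold (2.24 to 2.59). Fam50b was 4.0-fold lower (2.54 to 6.57), the complement gene C3 3.47-fold (2.11 to 5.97), Epha10 3.35-fold (2.08 to 5.61) and Gipr 3.08-fold (2.07 to 4.71), each from 118 reads or fewer. Tbx3 was 3.81-fold higher (3.02 to 4.85) and Insm1, a neuroendocrine transcription factor gene, 2.09-fold (1.81 to 2.41). Pcnxl2, Egfem1 and Trmt12 were 3.75-fold (2.06 to 7.21), 3.12-fold (1.78 to 5.71) and 2.35-fold higher (1.68 to 3.32) on 106 reads or fewer. Arhgap22 was 2.18-fold higher (1.87 to 2.55). The cluster named for Epo was 2.30-fold higher (1.83 to 2.90), but it spans several other genes, so its reads cannot be assigned to Epo.

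In this pair 15 of the 35 lists lay outside the central 95% of random lists, the study's presynaptic genes among them. Cholesterol synthesis genes had a median of -0.40 and glycolysis genes of -0.43, both at percentile 0, with Lss 2.13-fold (2.04 to 2.22) and Aldoc 2.09-fold lower (1.91 to 2.30). Interferon response genes had a median of -0.40 (percentile 0.01; -0.20 with a pseudocount of 5 CPM), immediate early genes of -0.26 (percentile 0.02), fibroblast and matrix markers of -0.37 (percentile 0.18; -0.08 with no filter on low values), astrocyte markers of -0.31 (percentile 1.24; -0.08 with no filter) and muscle and contractile genes of -0.19 (percentile 0.10). Mitosis genes and the unfolded protein list were each at -0.11 (percentiles 0.22 and 1.16). Above the random lists were neuronal RNA-binding protein genes (0.20, percentile 99.5), neuronal transcription factor genes (0.17, percentile 99.5), hnRNP genes (0.13, percentile 99.3), SR protein genes (0.11, percentile 98.7) and exosome and pore genes (0.12, percentile 97.8). DNA replication genes did not stand apart here (0.03, percentile 65.0). St18, a neuronal zinc finger gene, was at 0.87, and Ier3 was 2.25-fold lower (2.02 to 2.52). With a pseudocount of 0.1 CPM 90 genes were higher and 164 lower, and with 5 CPM 1 and 9.

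The difference from the control with both siRNAs went mostly the same way as with Ptbp1 siRNA alone. Of the genes tested in both pairs, 26 were higher in both knockdown libraries, out of 35 after Ptbp1 siRNA and 138 after both siRNAs, and 54 were lower in both, out of 61 and 355. Independent lists of these sizes among 13130 genes would share 0.37 and 1.65, and libraries simulated with counting noise alone against the same control shared 0. Such noise gives almost no calls at this size, so that 0 says nothing about variation between cultures. Across 9859 genes at a mean of 10 CPM or more, which are not independent replicates, the differences correlated at r = 0.83 (rho = 0.81), against r = 0.50 from the shared control in simulated libraries. Their covariance was 0.101 against 0.00336 simulated. As there was 1 control library, part of the overlap may come from what was particular to it. Both knockdown cultures also received siRNAs against Ptbp1, so effects of these siRNAs on other targets could not be told apart from loss of Ptbp1.

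Of the genes called after both siRNAs against control, 113 of the 147 higher and 270 of the 355 lower were called by size in neither single step. These genes were chosen by the sum of the steps. A sum just past 1 that is shared between the steps gives no call in either, so this count says little about step size. The median steps were 0.65, then 0.53, over the 147 higher genes and -0.64, then -0.59, over the 355 lower. A total of 88 genes differed by at least 0.58 in the same direction in both steps, 19 higher and 69 lower. Kdelr3 (-1.36, then -1.22), Iqgap1 (-1.13, then -1.41), Cyp4f13 (-1.04, then -0.98), Myo6 (-0.93, then -0.96), Lima1 (-1.21, then -0.93) and Aldoc (-0.92, then -1.05) had the largest smaller step. Another 38 genes went in opposite directions, 27 of them higher first. Ptbp2 led these (1.78, then -1.98), followed by Car6 (1.11, then -1.06), Esrp2, Cdh5, Prom2 and Itga7, which apart from Ptbp2 had 96 reads or fewer in any library. Across genes the steps correlated at r = 0.30 (rho = 0.29), where the shared Ptbp1 siRNA library alone gave r = -0.46 in simulated libraries.

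**Figure D3:**
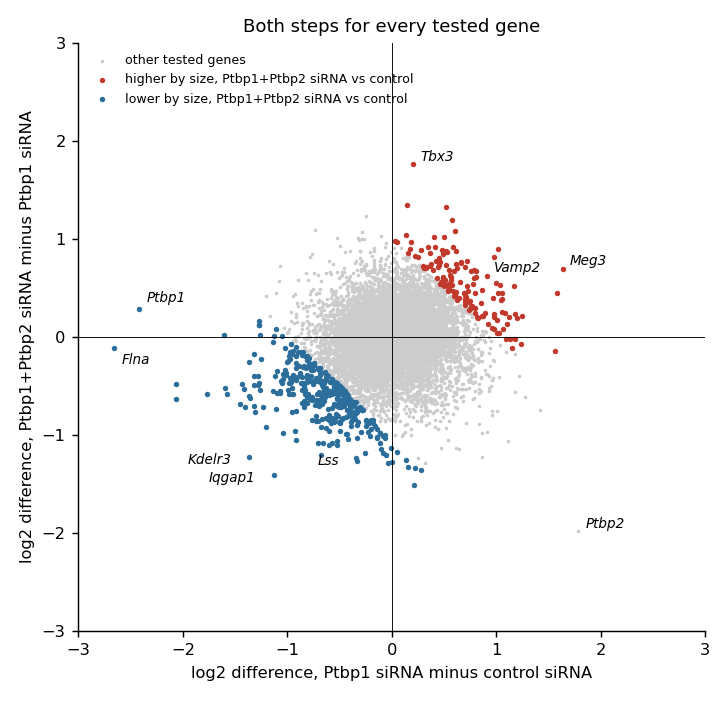
Log2 difference of Ptbp1 siRNA from control siRNA (x axis) against that of both siRNAs from Ptbp1 siRNA (y axis) for 13414 tested genes, coloured by the call of both siRNAs against control. The 355 lower and 147 higher genes were chosen by the sum of the steps, which by itself places most of them in the lower left and the upper right. Ptbp2 lies at 1.78 and -1.98.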

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

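In 178 genes the knockdowns lay on opposite sides of the control, each with a counting interval that excluded equality, mostly by small differences. Of these, 9 genes with at least 100 reads over the 3 libraries differed by at least 0.58 (log2) on the larger side and 0.1 on the smaller. With 1 library per group the difference between the knockdowns was not tested. The first value of each pair is the log2 difference of Ptbp1 siRNA from the control, the second that of both siRNAs. Ptbp2, the target of the added siRNA, was at 1.78 and -0.20, a gap of 1.98. Ddr2 was at 0.16 and -1.17 (gap 1.33), Gdf15 at 0.13 and -1.12 (gap 1.25) and Ect2, a gene of cytokinesis, at 0.18 and -0.82 (gap 1.00). Reep3 was at 0.20 and -0.62 (gap 0.82). Ndrg1, at 0.47 and -0.66 (gap 1.13), and Cyr61, at 0.62 and -0.52 (gap 1.13), had 19 and 53 reads after both siRNAs. Dkk1, a Wnt antagonist gene, went the other way, at -0.28 and 0.71 (gap -0.99), as did the cluster named for Epo at -0.74 and 0.36 (gap -1.09), whose reads overlap other genes.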

How the results depend on the processing

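No paired analysis was possible because each group had 1 library, and for the same reason no library could be left out. The read test without a limit of size and the limits of 1.5-fold and 3-fold moved the number of called genes most, followed by the pseudocounts, and the cause was not tested beyond what each setting's construction shows. Numbers below are higher then lower genes for Ptbp1 siRNA against control, both siRNAs against control, and both siRNAs against Ptbp1 siRNA, and then genes shared by both knockdowns against control. The values first reported were 37 and 61, 147 and 355, 14 and 44, and 26 and 54.

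A pseudocount of 0.1 CPM gave 158 and 138, 350 and 529, 90 and 164, and 83 and 98. A pseudocount of 5 CPM gave 4 and 26, 45 and 174, 1 and 9, and 3 and 25. A limit of 1.5-fold gave 391 and 461, 992 and 1312, 254 and 453, and 238 and 382. A limit of 3-fold gave 2 and 7, 9 and 47, 1 and 1, and 1 and 6. The binomial test of reads with Benjamini-Hochberg adjustment, which has no limit of size and compares libraries only, gave 2344 and 3078, 3684 and 3949, 2621 and 2392, and 1856 and 2518. With the deposited RPKM, added after seeing the data, the numbers were 15 and 40, 89 and 173, 11 and 24, and 9 and 34. A filter of 5 CPM gave 22 and 57, 113 and 319, 6 and 30, and 20 and 51. Removal of the GC, length and expression trend, also added later, gave 22 and 64, 121 and 328, 15 and 37, and 15 and 56.

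Under the other 9 settings no number moved by over 1.5 times. Median-of-ratios scaling kept all 502 called genes of both siRNAs against control, quantile normalization 454 and library totals 433. Of the list medians under alternatives 1340 stayed within their interval over genes and 10 left it. Of the values of named genes 2469 stayed within or close to their counting interval and 80 did not. No filter and the filter of 5 CPM leave a gene's own value as it was, so the 199 values under each stayed by construction. Some list medians moved widely all the same. Fibroblast and matrix markers after both siRNAs went from -0.54 to -0.05 with no filter and to -0.79 at 5 CPM, and against Ptbp1 siRNA from -0.37 to -0.08 with no filter. Astrocyte markers after Ptbp1 siRNA went from -0.45 to -0.18 with no filter, and between the knockdowns from -0.31 to -0.08. Neuronal transcription factor genes after both siRNAs went from 0.33 to 0.15 with no filter. After Ptbp1 siRNA, dense core granule genes went from -0.26 to -0.12 under quantile scaling. Ribosomal protein genes went from -0.14 to -0.07 under library-total scaling, and exosome and pore genes from 0.09 to 0.04 without overlapping clusters. With a pseudocount of 5 CPM, muscle and contractile genes after both siRNAs went from -0.28 to -0.15, and interferon response genes between the knockdowns from -0.40 to -0.20. Blood and endothelial markers after both siRNAs went from -0.33 to -0.02 and p53 response genes from -0.11 to 0.00 with no filter. Inside the central 95% of random lists, medians near 0 after both siRNAs changed sign under some settings: those of neuronal cytoskeleton and transport genes (-0.08, and 0.10 under quantile scaling), transcripts limited by nonsense-mediated decay (0.06, and -0.09 with the GC, length and expression trend removed), and voltage-gated channel, mitosis, oxidative phosphorylation, REST complex and unfolded protein genes. Among larger medians, the sign changed after both siRNAs for axon guidance and adhesion genes (0.17, and -0.06 without overlapping clusters). With the deposited RPKM it changed for oligodendrocyte and Schwann markers (0.14 to -0.03) and replication-dependent histone genes (-0.18 to 0.15). Decay-exon genes went from -0.60 after Ptbp1 siRNA and -0.61 after both to -0.16 and -0.19 without overlapping clusters. No list median outside the central 95% of random lists and no called gene among those named changed sign. Dropping the filter or the interval condition changed no call, because the size limit on the log2(CPM + 1) scale already leaves out genes with few reads. Depth limits genes near 1 CPM, where about 15 reads stand behind a value.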

Other observations

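The lists and single genes in the first 2 paragraphs were chosen after the values had been seen, so their medians are descriptions, and genes that had drawn attention were also left out to give a second value. Hypoxia-responsive genes outside the glycolysis list had a median log2 difference of -0.34 after Ptbp1 siRNA and -0.86 after both siRNAs over 23 members, none of them above 0 in the latter. Without Adm and Ndrg1 the medians were -0.35 and -0.86. P4ha1, a collagen prolyl hydroxylase gene, was at -1.39, Car9 at -1.45, Egln3 at -1.16 and Vegfa at -0.89, while Pfkfb3 was at -0.03. Fatty acid synthesis genes were at -0.34 and -0.66 over 15 members, with Acss2 at -1.59, Scd1 at -1.20 and Fasn at -0.91. Txnip, a gene induced by glucose, was 2.60-fold lower after Ptbp1 siRNA (2.39 to 2.82) and 4.05-fold lower after both (3.66 to 4.50). Ribosome biogenesis genes went the other way, with medians of 0.30 and 0.64 over 33 members, 28 and 33 of them above 0. Rrp12, Pop1 and Heatr1 were at 1.42, 1.5 and 1.00 and Polr1a, the largest subunit gene of RNA polymerase I, at 0.92. Each of these medians kept its sign under library-total, median-of-ratios and quantile scaling.

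Genes of collagen modification and the early secretory pathway had medians of -0.52 and -0.71 over 17 members, with Rcn3 at -2.03 and Creb3l2, a transcription factor gene of secretion, at -1.49 after both siRNAs. Without the 5 members that had drawn attention the medians were -0.25 and -0.52. In the imprinted region of Meg3, Mirg was at 0.19 and 0.24 and Rtl1 at -0.03 and 0.05, so the large differences seen there were those of Meg3 and Rian. Mirg had 24, 33 and 29 reads and Rtl1 15, 16 and 15, so differences in these genes could have been missed. Dlk1 and Dio3 had too few reads to be measured. Malat1, a nuclear noncoding RNA, had 32671, 20757 and 12602 reads, differences of -0.81 and -1.27 from the control. Of 8 mitochondrial clusters 7 were above the control after both siRNAs (6 under quantile scaling), mt-Nd4 at 0.62 and mt-Nd2 at 0.59, and mt-Co1 was at -0.12.

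The tests that follow were all chosen after the differences between the libraries had been seen. For the GC, length and expression trend in the first 2 patterns, what each outcome would mean was written down before the values with that trend removed were seen, and for the other tests after. Cholesterol synthesis genes had a median of -0.90 after both siRNAs. Once a trend in GC content, length and expression was removed, the median was -0.89 (-1.03 to -0.64 over genes). Across genes that trend was weak in this pair (rho = -0.06 for GC content, -0.07 for length and -0.01 for expression). A trend this weak did not account for the median, and its removal could hardly have moved it far. Under library-total, median-of-ratios and quantile scaling the median nearest to 0 was -0.81, so the choice among these scalings did not account for it. The scaling factors lay between 0.970 and 1.02, so library-total scaling could hardly have moved it far. All of these scalings are relative to the rest of each library, so a change in total RNA could not be judged. A shared culture state, such as cell number, oxygen or medium supply at harvest, is a candidate explanation that stays open, since the 21 hypoxia-responsive genes not noticed earlier had a median of -0.86 (-0.96 to -0.46) beside the lower sterol and glycolysis genes. The knockdown itself may equally lower these genes, and with 1 culture per group an effect of PTB proteins and a difference between cultures were not separated. No other siRNAs against Ptbp1 or Ptbp2 were used, so effects of the siRNAs on other targets were not separated either.

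The excess of lower over higher genes after both siRNAs was 355 against 147. Under library-total, authors' total, median-of-ratios and quantile scaling at most 40.3% of called genes were higher. The choice among these scalings therefore did not account for the whole excess at the 2-fold limit, but none of them could show a change in total RNA. The GC, length and expression trend was weak across genes in this pair, so its removal could hardly have moved the split. After that removal, which left out genes without a known GC content, 26.9% were higher (22.9 to 31.3, exact binomial). That interval treats called genes as independent, which they are not, and covers no variation between cultures. Loss of transcripts that PTB proteins stabilize or splice productively could give such an excess, but that was not tested, and the split depends in size on the scaling, the pseudocount and most of all the size limit. At 1.5-fold 43.1% were higher, and in the read test with no limit of size 48.3% (3684 against 3949), so the excess lay among the larger differences and nearly vanished without that limit.

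Vamp2, Sv2a and Kif5a were higher after both siRNAs while the wider set of release genes had a median near 0. A general rise of neuronal transcripts as the whole cause was taken to mean a median of at least 0.5 in the wider synaptic vesicle list. That mark was set after the values had been seen, and a general rise need not have that size. The median was 0.085 (-0.14 to 0.26 over 32 genes), so these release genes as a set did not rise as far as the 3 genes. The study chose the 3 genes, so a wider list could lie below them for that reason alone. The neuronal RNA-binding protein and transcription factor lists, at 0.43 and 0.33 (0.15 for the latter with no filter on low values), leave a smaller shared rise open. The median of Vamp2, Sv2a and Kif5a was 1.5 after removal of the GC, length and expression trend. As that trend was weak across genes in this pair, its removal could hardly have moved this median far. The pattern is consistent with regulation of these transcripts by PTB proteins, as a hypothesis, in libraries in which the study had followed them, and intron retention was not analysed here.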
